A study of Mus musculus with 8 samples.

How the data were processed

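The values were taken as deposited, as log2 expression per probe set for 8 arrays. Per the labels, total RNA was extracted from the mandibular arch at embryonic day 11.5 with a column kit, labelled with biotin by the standard Affymetrix procedure and came from mice of the C57BL/6J strain, with sex not determined. Per the submitters' processing notes the authors used RMA, which corrects background, equalizes the arrays' distributions and summarizes the probes of a set, and its version is not given in the sources used here. RMA compresses differences of dim probe sets, so a fold change from a low level is more apt to be too small than too large. Detection calls, scan dates and probe-level values were not used here.

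The table held 45101 probe sets. The platform annotation listed 1 gene symbol for 34958, several for 932 and none for 9211, and probe sets of the last 2 kinds were not named. Of the probe sets with 1 symbol, 34754 matched a gene of the mouse RefSeq table (GRCm38.p6) by Entrez identifier, and 0 changed name. No genome build is named with the values, so no coordinates are given, and the RefSeq table was used only for names and for which genes neighbour each other. Each gene was represented by its probe set with the highest mean over all arrays, which gave 18194 genes. Where another probe set of a named gene that was also bright had the opposite sign, this is stated.

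The 4 mutant arrays were compared with the 4 control arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on the log2 values, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all 18194 genes. A gene is said to rise or fall when its adjusted p is under 0.05. Adjusted p-values of single genes are from this fit. Errors are SD over arrays or the SE of the fitted change, as named. Changes are log2 fold changes, mutant minus control. The 27 gene lists held 478 genes, of which 449 were measured, and the others were not analysed here. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated for each list, and with fry, which tests whether the genes of a list move on balance one way. Some genes stand in more than 1 list. Tgfbr1 was also tested by an exact permutation of the group labels.

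The 27 lists, the design, the alternatives and the rule for named genes were fixed before the data were examined, except for 1 alternative and 4 further lists used in the closing section, which were added after. Counts of alternatives include the added one. That rule took Tgfbr1, the 12 largest rises and 12 largest falls past the threshold, up to 4 members of each list past the threshold by size of change, the 2 members with the smallest p where none passed, and Xist and the Y-linked genes. Further list members named with a log2 fold change only, the myogenic regulators, and genes named in the closing section outside that rule were chosen after their values were seen. The Y-linked gene Ddx3y was not analysed here. The p-values of the 4 further lists were adjusted over those 4 alone, not together with the 27. Among the 4 was a list of platelet genes already seen to be lower, which can lower the adjusted p of the others.

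The steps were tested on simulated arrays made from the real genes' means and spreads. In 10 runs over 18194 genes with 200 changed, 49.0% of genes changed by 0.5 on the log2 scale, 89.0% of those changed by 1 and 99.4% of those changed by 2 were recovered, and 4.36% of the calls were false. A list of 20 genes shifted by 0.5 had an unadjusted camera p under 0.05 in 10 of 10 runs and an unshifted list in 0. The lists below were called at an adjusted p, and most of those called had medians smaller than 0.5 in size. The simulated spread was independent between genes, unlike that of real arrays. Alternatives included the replicate number as a block, other ways to choose probe sets, filters on dim genes, further normalization, other variance models, array weights, a sex score, other thresholds and leaving out each array in turn.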

Results

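RNA from the mandibular arch of mouse embryos at embryonic day 11.5 was measured on 8 Affymetrix arrays, 4 from Alk5 fl/fl controls and 4 from Wnt1-Cre;Alk5 fl/fl mutants. The mandibular arch is the embryonic tissue that gives rise to the lower jaw. Its mesenchyme comes largely from cranial neural crest cells, and its muscles come from mesodermal precursors. Alk5 is another name for Tgfbr1, the type I receptor for TGF-beta, and the Wnt1-Cre driver inactivates the floxed gene in the neural crest lineage. The comparison of mutants with controls addressed how inactivating Alk5 in neural crest cells affects the arch in which they meet the myogenic precursors. The control labels name no Cre driver, so an effect of the driver itself cannot be told apart from that of the inactivation. The median log2 value of an array lay between 6.28 and 6.42. Mutant replicate 3 stood apart, with a standard deviation of 2.42 over all probe sets against 2.52 to 2.56 on the other arrays and a lowest correlation with another array of 0.986. Without it, pairs of arrays correlated at 0.993 to 0.997. The number of arrays limits the precision of every value below. The labels number the samples without stating that each came from a different embryo or litter. The sex-linked genes below show both sexes in each group, so the arrays of a group did not all come from the same source. The p-values measure only the spread between these samples, part of which may be technical.

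Tgfbr1, the targeted gene, was not lower in the mutants. Its brightest probe set (1420895_at) read 12.79 ± 0.0844 in controls and 12.98 ± 0.0115 in mutants (SD, n = 4 each), a log2 fold change of 0.19 with a 95% interval of 0.04 to 0.34 (limma adjusted p = 0.232; two-sided exact permutation p = 0.0286, the smallest that 70 relabelings can give). A second probe set (1420893_a_at) differed by 0.51 (exact permutation p = 0.0857) and the third (1420894_at) by 0.30 (exact permutation p = 0.2). The arrays read the 3′ part of a transcript and the arch also holds cells outside the Cre lineage, and which exon is floxed and whether the probe sets lie outside it is not known here, so these probe sets are not taken as a test of the deletion. With a mean-variance trend and robust variance the adjusted p of the brightest probe set was 0.028, with the mutants higher.

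Of 18194 genes, 390 differed between mutant and control arches at an adjusted p under 0.05, of which 152 were higher and 238 lower in the mutants. Igdcc3, an immunoglobulin superfamily receptor, rose 11.3-fold, from 8.72 ± 0.894 to 12.22 ± 0.138 (log2 value, SD, n = 4, adjusted p = 0.00271). Lin28a, an RNA-binding protein that blocks maturation of the let-7 microRNAs, rose 5.91-fold, from 5.01 ± 0.292 to 7.57 ± 0.665 (adjusted p = 0.004). Protogenin (Prtg) rose by 2.24 ± 0.252, the stem-cell ubiquitin ligase gene Trim71 by 2.11 ± 0.244 and the zinc finger gene Sall4 by 1.87 ± 0.219 (log2 fold change ± SE). The homeobox gene Gbx2 rose by 1.84 ± 0.313, and Foxc1, a forkhead factor of cranial mesenchyme, by 1.99 ± 0.269. The other genes among the 12 largest rises were Csn3 (2.33), Ms4a6d (1.87), the antisense transcript Dlx4os (1.80), the muscle enolase gene Eno3 (1.77) and the arginase gene Arg1 (1.77). On Igdcc3, Lin28a, Trim71, Prtg and Sall4, control replicate 4 lay at a median of 0.315 of the way from the other controls to the mutants, whereas the other controls lay at -0.221 to -0.0406. Igdcc3 has a further bright probe set that did not rise with the others, and its log2 fold change over the mean of its probe sets was 1.79. Over the mean of their probe sets Lin28a rose by 1.46 and Csn3 by 1.15, and the control levels of both lay near the lower quartile of the arrays.

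Among the falls, Cbln4, a secreted cerebellin, dropped 8.78-fold, from 8.58 ± 0.85 to 5.45 ± 0.376 (SD, n = 4, adjusted p = 0.00457). The leptin receptor gene Lepr fell by 2.62 ± 0.391 on the log2 scale (± SE), as did the monoamine oxidase gene Maob (-2.46 ± 0.348). Of the same 12, 6 were transcription factor genes. Hey2, a Notch target, changed by -2.27 ± 0.443, Tbx18 by -2.11 ± 0.365 and Nfix by -2.08 ± 0.373. Pax3 went from 9.71 to 7.70, Meox2 from 9.27 to 7.27, and Pax9, which is required for teeth and palate, from 9.19 to 7.20. Fibin (-2.04), Otor (-1.92) and the unnamed transcript AI606473 (-1.90) completed the 12 largest falls. Over the mean of their probe sets Lepr was at -1.27, Nfix at -1.06 and Pax9 at -1.22. On the 238 genes that fell, control replicate 4 lay at a median of 0.332 of the way from the other controls to the mutants, and the other controls lay at -0.216 to 0.0112.

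**Figure D1:**
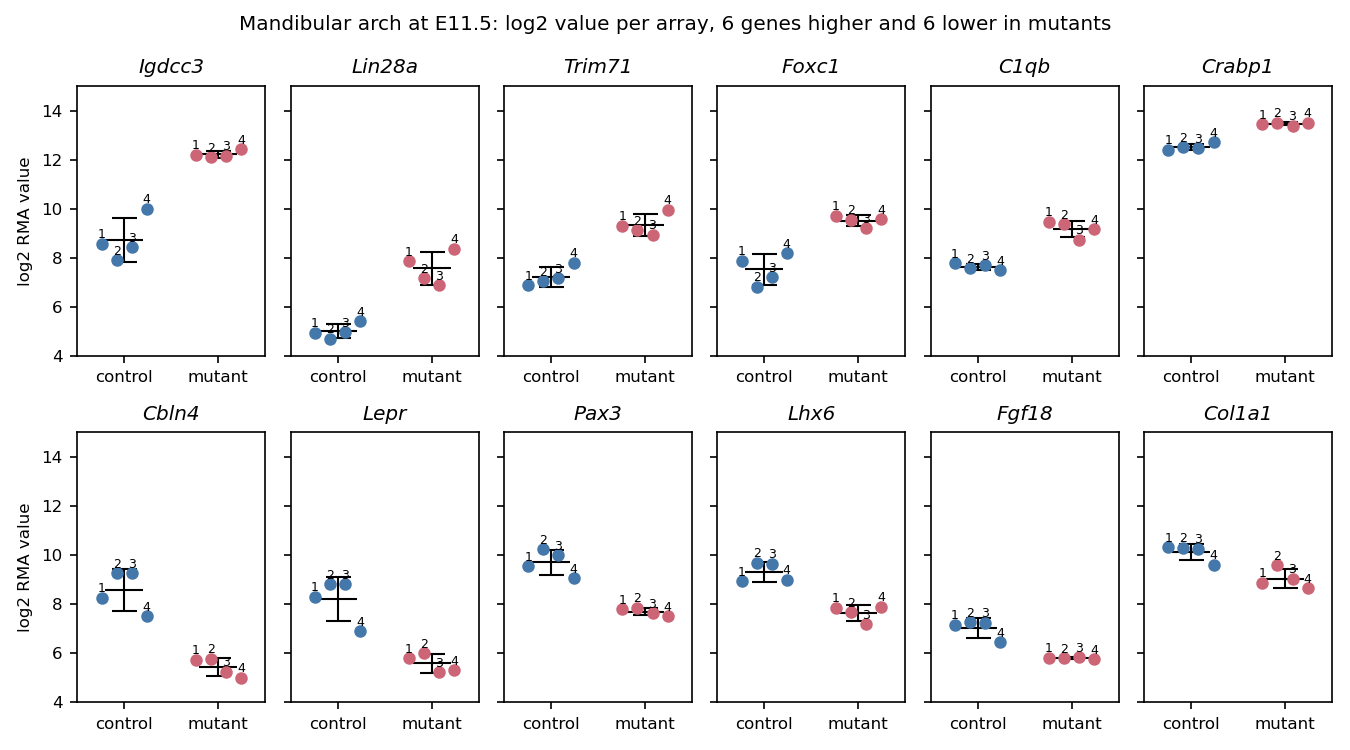
Log2 RMA value (y axis) of 12 genes on each array of 4 controls (blue) and 4 mutants (red), with the replicate number above each point, the group mean as a horizontal line and the SD as the error bar. The groups did not overlap for any gene plotted, and control 4 was the control nearest to the mutants for Igdcc3 and Lin28a and for Cbln4, Lepr and Pax3.

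The changes were tested with limma's moderated model, and 386 of the 390 genes had no overlap between the groups. Over all genes 1872, or 10.3%, had none, where 2.86% would by chance. The number of genes depended on the arrays used: it was 618 without mutant replicate 3 (328 higher and 290 lower), but 151 without control 1 (85 and 66), 109 without control 2 (64 and 45), 104 without control 3 (60 and 44), 198 without mutant 1 (83 and 115) and 108 without mutant 4 (68 and 40). Rises thus outnumbered falls without control 1, 2 or 3 or mutant 3 or 4, the reverse of the balance over all arrays. Of the 12 largest rises, 10 passed under each alternative that measured them, while Gbx2 lost its call without control 1, 2 or 3 or mutant 1 or 4 and Dlx4os without control 2 or 3 or mutant 1, 2 or 4. Of the 12 largest falls, 5 passed throughout (Cbln4, Maob, Fibin, Pax3 and AI606473). Hey2 lost its call without any array but control 4, Nfix without control 1, 2 or 3 or mutant 1 or 4, Tbx18 and Meox2 without control 1, 2 or 3 or mutant 4, Lepr without control 2 or mutant 4, Otor without control 2 and Pax9 without mutant 4. Among list members below, Aldh1a2, Col1a2 and Sfrp2 lost the call without control 1, 2 or 3 or mutant 1 or 4, Pf4 without control 2 or 3 or mutant 1, 2 or 4, Gli1, Skil and Wnt9a without control 1, 2 or 3 or mutant 4, Ccn2 without control 2 or 3 or mutant 1 or 4, Fst and Hspa1b without control 1, 2 or 3, Bmp4, Cyp26b1 and Lef1 without control 2 or 3 or mutant 4, Bmpr1b and Tubb3 without control 3 or mutant 4, and Eya1 without control 3. Over the mean of a gene's probe sets the change was more than 1.5 times smaller for Osr2 (-0.75), Foxf2 (-0.36), Wnt9a (-0.50), Bmpr1b (0.84), Lhx6 (-1.11), Ltbp1 (-0.56), Eya4 (-0.62), Eya1 (-0.47), Erg (-0.33) and Skil (-0.29), and Foxf2, Ltbp1, Erg and Skil then did not pass. Of all 72 named genes past the threshold, 44 lost the call under at least 1 alternative, and every one of the 72 kept its direction.

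Markers of macrophages and other leukocytes rose together. Of 16 measured, 11 rose, 1 fell and 4 did not pass, with a median log2 fold change of 0.82 (15 passed when adjusted over the list alone). The complement genes C1qb, C1qc and C1qa, which tissue macrophages make, rose by 1.54 ± 0.149, 1.52 ± 0.149 and 1.40 ± 0.131, and Adgre1, which encodes the F4/80 antigen, by 1.21 ± 0.13 (± SE). The member that fell was Pf4, a platelet gene (-0.77 ± 0.138). The list was shifted upward by limma's camera test (adjusted p = 7.9e-22) and by fry (adjusted p = 0.00108), with an adjusted p = 0.0642 with an estimated correlation. Erythroid genes shifted the other way (median -0.17, camera adjusted p = 0.00694, adjusted p = 0.521 with an estimated correlation), although 0 of 13 passed singly, nor did any adjusted over the list alone. The erythroid genes with the smallest p, Nfe2 (-0.45, adjusted p = 0.127) and Epb42 (-0.59, adjusted p = 0.212), did not pass. The erythroid call was lost without control 4 (adjusted p = 0.0536), without mutant 2 (0.0832), with the sex score as a covariate (0.0644) and over genes above the median level (0.221), within a range of 6.2e-04 to 0.221 over the alternatives.

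Extracellular matrix genes were lower. All 26 measured had a log2 fold change below 0, with a median of -0.37; 6 fell, 12 did so adjusted over the list alone, and 20 did not pass over all genes. Lumican (Lum) fell by 1.61 ± 0.331, the collagen VI genes Col6a2 and Col6a1 by 1.32 ± 0.264 and 1.14 ± 0.24, and Col1a1 by 1.08 ± 0.216 (± SE), with Col1a2 (-0.91) and Bgn (-0.83) as the remaining falls. The list was shifted by camera (adjusted p = 1.2e-10; adjusted p = 0.521 with an estimated correlation). Lum, Col6a2, Col6a1 and Col1a1 each lost the call without control 1, 2 or 3 or mutant 1, 3 or 4, with adjusted p-values up to 0.151, 0.135, 0.159 and 0.14 over the alternatives. In the same mutant arrays the macrophage list was higher, by a median of 0.82.

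Genes known to respond to TGF-beta were lower as a list, with a median of -0.17 over 26 measured and 23 below 0 (camera adjusted p = 9.7e-05, or adjusted p = 0.521 with an estimated correlation), in arrays in which the macrophage list was higher by a median of 0.82. Of the 26, 3 fell, 1 rose and 22 did not pass, and 9 passed adjusted over the list alone. The falls were Col1a1 and Col1a2, which encode the chains of type I collagen and are also in the matrix list, and Skil (-0.54 ± 0.0903), a feedback inhibitor of Smad proteins. The rise was Ccn2 (0.74 ± 0.124), a matricellular protein gene that TGF-beta induces in many cells. Among 25 components of the pathway itself, the activin antagonist follistatin (Fst) fell by 1.65 ± 0.261 and the latent TGF-beta binding protein gene Ltbp1 by 0.97 ± 0.185, while the activin receptor gene Acvr2b rose by 0.52 ± 0.107. Acvr2b lost its call in 10 of 20 alternatives, among them without control 1, 2 or 3 or mutant 1, 2 or 4 (adjusted p up to 0.155), and Ltbp1 in 7 of 20, among them without control 1, 2 or 3 or mutant 1, 3 or 4 (up to 0.122). The remaining 22 components did not pass (6 passed adjusted over the list alone), and that list was not shifted (camera adjusted p = 0.228).

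Signalling lists with lower levels in the mutants were WNT, Hedgehog and BMP. Of 26 WNT genes, 5 fell, 0 rose and 21 did not pass, with a median of -0.36 (11 passed adjusted over the list alone). Wnt5a, a ligand of outgrowing arch mesenchyme, fell by 0.95 ± 0.193, Wnt9a by 0.91 ± 0.16, the nuclear effector Lef1 by 0.85 ± 0.14 and Sfrp2 by 0.83 ± 0.154 (± SE), and Rspo2 was the other fall (-0.40). Wnt5a lost its call without any array but control 4 (adjusted p up to 0.15 over the alternatives). The camera adjusted p was 1.9e-08, and the adjusted p = 0.521 with an estimated correlation. Of 15 Hedgehog genes, Osr2 (-1.55 ± 0.208), Foxf2 (-0.68 ± 0.0966) and the target Gli1 (-0.51 ± 0.0928) fell and 12 did not pass (6 passed adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.00166; adjusted p = 0.521 with an estimated correlation). Of 22 BMP genes, the ligand gene Bmp4 fell by 1.16 ± 0.174 and the receptor gene Bmpr1b rose by 1.34 ± 0.213, while 20 did not pass and 7 did so adjusted over the list alone. The BMP median was -0.15 (camera adjusted p = 0.00363; adjusted p = 0.521 with an estimated correlation). Over genes above the median level the Hedgehog (adjusted p = 0.221) and BMP (0.175) calls were lost, the highest values in ranges that began at 3.7e-04 and 6.5e-04. Macrophage genes were higher in the mutants here too, by a median of 0.82.

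Fgf18 was the single member of 24 FGF genes to pass, and it fell by 1.23 ± 0.166, to a mutant level of 5.80 ± 0.0377 (SD, n = 4); 3 passed adjusted over the list alone and the list was not shifted (median -0.08, camera adjusted p = 0.316). Retinoic acid genes moved both ways. Crabp1 and Crabp2, which encode cellular retinoic acid binding proteins, rose by 0.94 ± 0.0815 and 0.33 ± 0.0664, whereas the degrading enzyme gene Cyp26b1 fell by 1.47 ± 0.227 and the synthesizing enzyme gene Aldh1a2 by 1.16 ± 0.214. Crabp2 lost its call in 10 of 20 alternatives, among them without control 1, 2 or 3 or mutant 1, 2 or 4 (adjusted p up to 0.167), and Crabp1 in 0. The other 8 of the 12 measured did not pass, 4 passed adjusted over the list alone, and the median was -0.12 (camera adjusted p = 0.545).

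Genes that pattern the arch, all but Edn1 transcription factors, also moved both ways. Of 23 measured, 4 rose, 4 fell and 15 did not pass (13 passed adjusted over the list alone), and the list as a whole was not shifted (median -0.06, mean 0.01, camera adjusted p = 0.766). Lhx6 and Lhx8, LIM-homeobox genes of the oral side of the arch, fell by 1.67 ± 0.214 and 1.36 ± 0.147. Dlx4 rose by 1.53 ± 0.297 and Gbx2 by 1.84 ± 0.313, and Dlx3 (1.35), Dlx2 (0.56), Pitx1 (-1.10) and Alx1 (-0.99) were the other members past the threshold. Dlx4 lost its call without any array but control 4 (adjusted p up to 0.122 over the alternatives). Hox genes, which mark the arches behind the mandibular one, were above 0 in 8 of 8 (median 0.14, camera adjusted p = 0.00363; adjusted p = 0.521 with an estimated correlation), and 1, Hoxb2, rose singly (0.83 ± 0.12), or 2 adjusted over the list alone. Without mutant replicate 3 (adjusted p = 0.103) and with array weights (0.0637) the Hox call was lost (in a range of 0.00106 to 0.116). Over genes above the median level too few Hox genes remained to test the list, so most of its members were dim. Macrophage genes were higher beside it, by a median of 0.82.

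Cartilage, bone and tendon genes had a median of -0.42 over 17 measured, but the members that passed went opposite ways: the cartilage collagen gene Col9a1 rose by 1.02 ± 0.147 and Col1a1, shared with the matrix list, fell, while 15 did not pass and 8 did so adjusted over the list alone. The camera adjusted p of 0.0134 became an adjusted p = 0.521 with an estimated correlation. The macrophage list was higher in the same mutant arrays, by a median of 0.82. The call was also lost without control 3 (0.0511), without mutant 3 (0.0719) and over genes above the median level (0.935), in a range of 0.00191 to 0.935.

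Most markers of the muscle lineage did not pass. Of 18 markers of craniofacial myogenic precursors, 3 fell and 15 did not pass (4 passed adjusted over the list alone). These were Pax3, which fell 4.01-fold, and the eyes-absent family genes Eya4 (-0.93 ± 0.118) and Eya1 (-0.76 ± 0.11). Pax3 and the Eya genes are not specific to muscle precursors and are known from neural crest derivatives or placodes too. The myogenic regulators Myf5 (0.30, adjusted p = 0.66), Myod1 (-0.01, adjusted p = 0.99) and Myog (-0.03, adjusted p = 0.99) did not pass. The list was not shifted (camera adjusted p = 0.791), its median of 0.08 being above 0 and its mean of -0.11 and the direction of the test below. Of 32 genes of differentiating skeletal muscle, 0 passed, over all genes or adjusted over the list alone, and the median was 0.06 (camera adjusted p = 0.232). The smallest p belonged to Tpm2 (0.30 ± 0.101, adjusted p = 0.202) and Des (0.30 ± 0.102, adjusted p = 0.221). This list was shifted upward without control 1 (adjusted p = 3.0e-07) and without mutant 4 (0.00427), in a range up to 0.939.

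**Figure D2:**
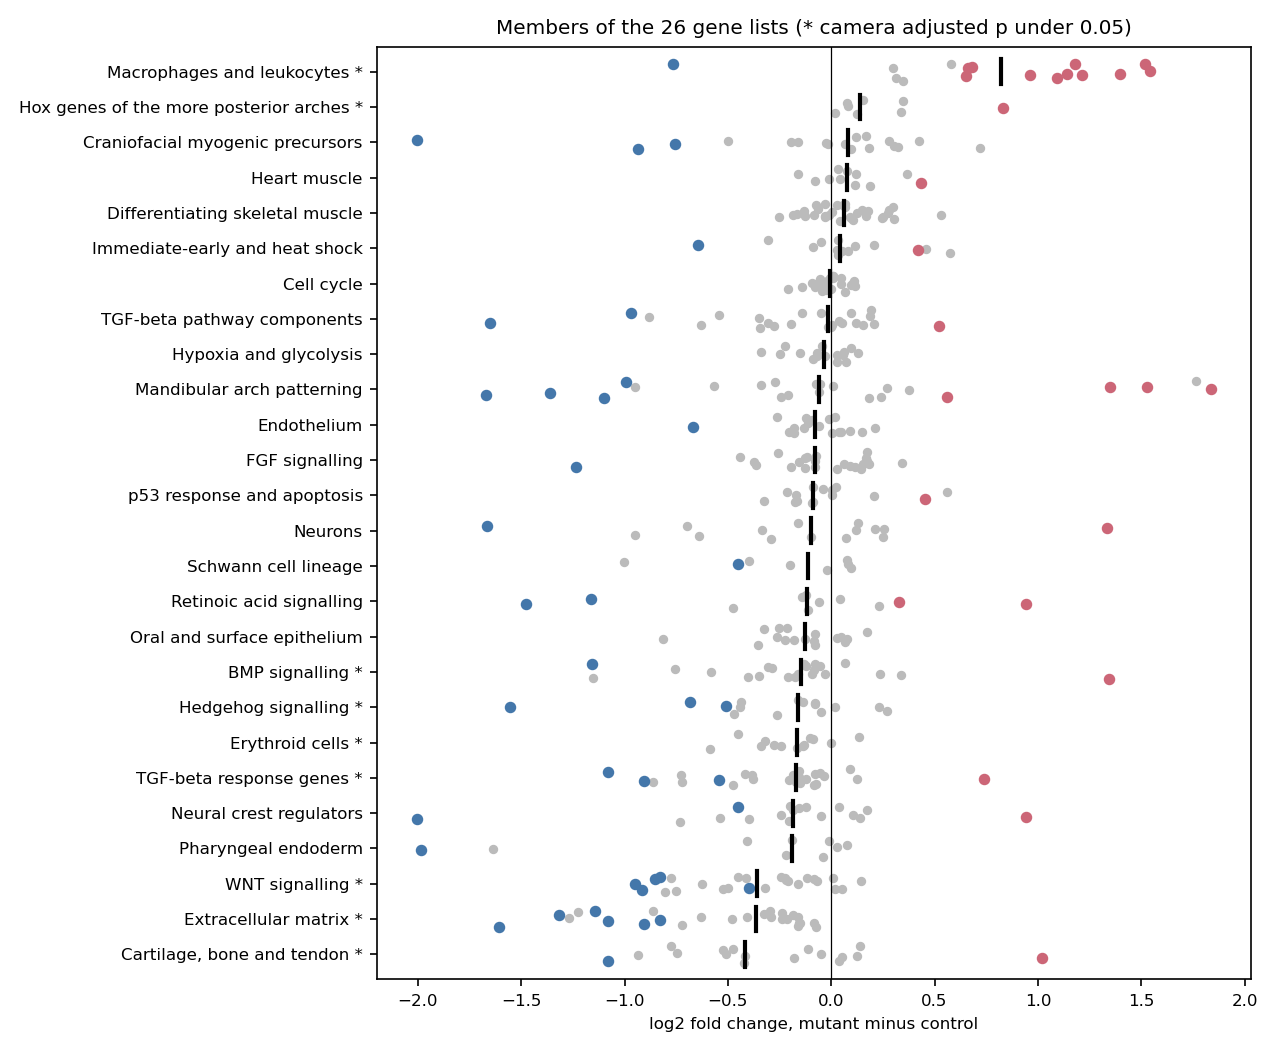
Log2 fold change, mutant minus control (x axis), of each measured member of the gene lists, with the sex-linked list left out. Red and blue points rose or fell at an adjusted p under 0.05, grey points did not pass, black bars are list medians, and an asterisk marks lists shifted by camera with the preset correlation. Macrophage genes lie to the right (median 0.82), and matrix and WNT genes to the left (-0.37 and -0.36).

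Among 17 neural crest regulators, Pax3 and Foxd3 (-0.45 ± 0.0933) fell, Crabp1 rose and 14 did not pass (5 passed adjusted over the list alone, median -0.18, camera adjusted p = 0.0532). Foxd3 was also the single fall among 8 Schwann cell lineage genes (camera adjusted p = 0.197, 2 adjusted over the list alone). Of 15 neuronal genes, Gap43, a growth cone protein gene, rose by 1.34 ± 0.0709 with the smallest adjusted p of all genes (1.27e-04), and Tubb3 fell by 1.67 ± 0.249, while 13 did not pass (4 adjusted over the list alone, median -0.10, camera adjusted p = 0.796). Pax9 was the 1 fall among 9 pharyngeal endoderm genes (2 adjusted over the list alone, camera adjusted p = 0.0532), and Myl7 the 1 rise among 11 heart muscle genes (0.43 ± 0.0848, 1 adjusted over the list alone, camera adjusted p = 0.0534). Myl7 lost its call in 12 of 19 alternatives, among them without any array but mutant 3 (adjusted p up to 0.145), and Foxd3 in 9 of 19, among them without any array but control 4 (up to 0.156). Of 18 endothelial genes, Erg fell (-0.67 ± 0.14), although its other bright probe set had the opposite sign, and 17 did not pass (2 adjusted over the list alone, camera adjusted p = 0.321). Erg lost its call in 9 of 20 alternatives, among them without control 1, 2 or 3 or mutant 1 or 4 (adjusted p up to 0.163). In 17 genes of oral and surface epithelium 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.249), the smallest p being those of Krt14 (-0.81, adjusted p = 0.267) and Cldn3 (0.17, adjusted p = 0.459).

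Cell cycle genes did not differ past the threshold. Of 24 measured, 0 passed over all genes or adjusted over the list alone, with Ccnd3 (-0.21, adjusted p = 0.314, its other bright probe set having the opposite sign) and Ccne2 (-0.14, adjusted p = 0.518) closest, and the list was not shifted (median -0.0038, direction of the test upward, camera adjusted p = 0.766). Of 15 genes of the p53 response and apoptosis, Bbc3, which encodes the BH3-only protein PUMA, rose by 0.45 ± 0.0839 (2 passed adjusted over the list alone), while the median was -0.09 and the direction of the test upward (camera adjusted p = 0.969). Among 14 immediate-early and heat shock genes Atf3 rose by 0.42 ± 0.0792 and Hspa1b fell by 0.65 ± 0.109 (4 adjusted over the list alone, camera adjusted p = 0.275). Atf3 lost its call in 9 of 19 alternatives, among them without any array but mutant 3 (adjusted p up to 0.122), and Bbc3 in 6 of 20, among them without any 1 of the controls or mutant 1 (up to 0.12). Of 16 hypoxia and glycolysis genes 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.738), with Vegfa at -0.25 (adjusted p = 0.121, its other bright probe set having the opposite sign) and Egln3 at -0.34 (adjusted p = 0.575).

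Over the 27 lists, camera with its preset correlation called 9, of which 2 were up and 7 down, 0 with an estimated correlation, and fry called 1. Xist was at the high level in controls 1, 3 and 4 and mutants 3 and 4, and the Y-linked genes Eif2s3y, Kdm5d and Uty in control 2 and mutants 1 and 2, so both groups held both sexes, and no member of the sex-linked list passed over all genes or adjusted over the list alone (camera adjusted p = 0.545; Xist -1.60, adjusted p = 0.735).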

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

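The tests of muscle differentiation, carried-over blood, the share of crest mesenchyme, dying cells and a compressed intensity range were chosen only after the results they measure had been seen, and that on the spread among controls was prompted by the position of control 4 on the genes that fell.

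In 15 of 196 groups of 4 arrays (7.65%), 1 array stood far from the rest, where chance gives about 1 in 20. Of the 15, 4 were sex-linked genes in control replicate 2, which reflect 1 difference. Genes are not independent either, so the share is not read as an excess. Control replicate 4 was the low array for 6 genes that fell in the mutants: Col1a1 (9.61, other controls 10.27 to 10.32), Fgf18 (6.45), Fibin (8.96), Fst (9.45), Nfix (9.19) and Wnt9a (7.10). Control replicate 1 was high for Des (7.74) and Skil (10.98). Control replicate 2 was high for Eif2s3y (8.64), Kdm5d (8.99) and Uty (8.67) and low for Xist (6.62), being the single control with high Y-linked genes. Mutant replicate 3 was low for Gbx2 (7.50) and Zic2 (4.28) and in its mean correlation with its own group (0.989, others 0.994). Among 10092 probe sets without 1 gene symbol, which the comparison of genes did not use, 15 passed the threshold, 6 higher and 9 lower in the mutants.

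Chance in the grouping of arrays was tested with all 35 splits of the 8 arrays into 4 and 4. Only the real split, 1 of 35, gave as many as 390 genes, and the highest of the others gave 0. Each other split mixes controls with mutants, so a real difference widens the spread within its groups and calls are unlikely there. The smallest share that 35 splits can give is 1 of 35. The splits therefore cannot exclude chance as the source of that number, and they cannot address a stage, litter or batch that differs between the groups.

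Lin28a, Trim71, Prtg, Igdcc3 and Sall4 were higher in the mutants, with a median log2 fold change of 2.24. Neural tube tissue carried over is argued against, since 12 measured neural progenitor genes, of which Sox2 (9.50 in controls) and Nes (9.17) were the brightest, had a median of 0.034 (camera adjusted p = 0.25, quartile spread 0.169), although 1 of them, Zic2, passed (adjusted p = 0.0436) at levels of 4.02 and 4.37, below the lower quartile of every array, where no change can be read. A younger stage of the mutant embryos may contribute: 13 other early-embryo genes had a median of 0.19 with 8 above 0 (camera adjusted p = 0.0194, adjusted p = 0.0828 with an estimated correlation), though 0 of them passed singly (3 rose adjusted over the list alone, fry adjusted p = 0.0146), and control 4, at 0.332 on the fallen genes, lay at 0.315 on the 5 genes against at most -0.0406 for another control, a position not particular to early genes, since over all genes that rose it lay at 0.165 against at most 0.0264. Clocks outside the Cre lineage left stage open. The globin score, the mean of Hbb-bh1 and Hba-x minus that of Hbb-y and Hba-a1, would be higher at a younger stage. It differed by -0.18, toward lower in the mutants (exact permutation p = 0.171). The probe set used for Hba-a1, however, read at background (4.65), which may not be the level of the gene. Hbb-y was near the top of the scale (14.89). Muscle differentiation genes, which would be lower at a younger stage, had a median of 0.062 (camera adjusted p = 0.232). That list passed in 2 of 19 alternatives, upward each time. Neither clock thus moved toward a younger stage, but neither passed over all arrays. A delay caused by the genotype and a difference in the embryos' age at harvest cannot be told apart with the globin and muscle genes, because neither set passed and the globin probe sets limit the score. The labels give no finer stage either.

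Macrophage markers were higher in the mutants, by a median of 0.82. Blood carried over is argued against by the direction of 13 erythroid genes, which had a median of -0.17 (camera adjusted p = 0.00694), where blood that brought the macrophage genes would raise them. The list was past the threshold in 15 of 19 alternatives and downward in all 19, but these reuse the same arrays. The adjusted p was 0.521 in camera with an estimated correlation and 0.174 by fry, so the argument rests on the preset correlation. A lower share of crest mesenchyme would raise the markers of every other cell type alike, but the macrophage median exceeded the highest of the endothelial, epithelial and erythroid medians (-0.08) by 0.90, more than its own quartile spread of 0.67. A response to dying cells stays open, since 15 genes of the p53 response and apoptosis had a median of -0.087 with members on both sides (camera adjusted p = 0.969) and transcripts cannot show cell death directly. More macrophages, or more active ones, in the mutant arch may account for the rise as a hypothesis, and control 4 did not share it (-0.106 of the way to the mutants), unlike its position on the early-embryo genes (0.315).

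Mutant replicate 3 stood apart from the other arrays. Degraded RNA is argued against, since its 3′ minus 5′ difference for Gapdh was -0.0787, within the -0.132 to 0.0038 of the other arrays, and that for Actb was 0.334, also within their range. A compressed intensity range may account for part of it: the slope of its values on the mean of the other mutants was 0.936, against 0.993 to 1.03 for the other arrays, and its bioB hybridization controls averaged 8.31 against 8.79 to 9.08. The lys and phe controls of mutant replicate 3 were lower too, at 6.21 against 7.07 to 7.86 and 6.84 against 7.69 to 8.56. The cause of these lower controls was not tested. A stronger phenotype stays open, since its deviation correlated with the effect in mutant 4 at 0.196 across genes, which are not independent replicates. A linear trend on the mean level was first removed from both. It cannot be told apart from a compressed range, because both could move the same genes.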

How the results depend on the processing

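The combination of quantile normalization with mutant replicate 3 left out was added after seeing the data, and the other alternatives were fixed before. Of the 390 genes, all that an alternative still tested kept their direction (241 above the median level and 361 above the lower quartile), except that without probe sets ending in _x_at or _s_at 385 of 388 did. The count of changed genes was 620 after quantile normalization (353 shared), 1356 with array weights, 664 at an adjusted p under 0.10 and 678 under the added combination (362 shared). Genes higher numbered 92 above the median level, 279, 629, 232 and 337 in the settings just named, and genes lower 369 with a variance trend and robust fit, 727 with array weights, 396 with the sex score and 432 at 0.10. Leaving out 1 array gave 104 to 618 genes changed (without control 3 and mutant 3), 60 to 328 higher (control 3 and mutant 3) and 40 to 357 lower (mutant 4 and control 4), with 103 of the 104 among the 390. Array weights gave mutant 3 a weight of 0.108. The looser threshold accounts for its own counts, and for the others the cause was not tested. Deviations from the group mean correlated at 0.0327, 0.0019, -0.124 and 0.406 between the control and the mutant of replicates 1 to 4. On Lin28a, Trim71, Prtg, Igdcc3 and Sall4, control 4 was the highest control and mutant 4 the highest mutant. Arrays of unlike number were not compared, so whether the replicate 4 arrays share a litter or stage is not known here. With the replicate number as a block 293 genes passed, 251 of them among the 390.

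Camera called 4 lists over genes above the median level, 0 with an estimated correlation, and fry 1. Macrophage, matrix, WNT and TGF-beta response lists passed in each of 19 camera settings at the preset correlation. Lists that were not called and passed elsewhere were neural crest regulators (7 of 19 settings, among them without control 4, mutant 1 or mutant 2, adjusted p 0.00833 to 0.808), pharyngeal endoderm (11 of 19, among them without control 1, control 4 or mutant 2, 0.00890 to 0.215), heart muscle (6 of 18, among them without control 1, mutant 1 or mutant 4, 0.00264 to 0.513), Schwann cells without control 4 (0.0169 to 0.81), epithelium without mutant 1 (0.0344 to 0.758) and muscle differentiation without control 1 or mutant 4 (3.0e-07 to 0.939). Tgfbr1 (0.19) passed with the trend and robust fit (adjusted p 0.0282 to 0.49). Of 72 named genes past the threshold, 28 passed in all their alternatives and 44 lost the call in some, and 193 of 576 gene calls were lost when 1 array was left out. Eif2s3y (-0.21) and Kdm5d (-0.11) reversed with the sex score as a covariate, which is void for them since the score is built from them. Signal over background limits Lin28a and Csn3, whose control levels (5.01 and 5.17) lie near the lower quartile of the arrays.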

Other observations

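The test on neighbouring genes was chosen only after the result was seen, and the genes below were picked after their values were seen.

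Outside the lists, Gata2 rose by 1.31, Dach2 by 1.26 and Chd7, a chromatin remodeler mutated in CHARGE syndrome, by 0.89 on the log2 scale, while Shox2 fell by 1.38, Klf4 by 1.25, Osr1 by 1.18, Six2 by 1.15 and Bcl11b by 1.15. Each had an adjusted p under 0.05 over all genes in limma.

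Platelet genes went against the macrophage genes. Ppbp fell by 0.97 ± 0.169, Tubb1 by 0.79 ± 0.144, Rgs18 by 0.78 ± 0.131 and Pf4 by 0.77 ± 0.138 (± SE), and Itga2b (-0.24) and Gp9 (-0.28) did not pass. Ppbp lost its call without control 2 or mutant 1 or 4, Tubb1 without control 2 or mutant 1, 2 or 4 and Rgs18 without control 2 or mutant 4. Fewer platelets or megakaryocytes in the mutant samples may account for this as a hypothesis. A list of 12 further platelet genes, made before their values were read but after the 390 genes were known, had a median of -0.18 with 10 below 0. Over the 4 added lists alone its camera adjusted p was 0.0194, but the adjusted p = 0.136 with an estimated correlation. The platelet genes named above had been left out of it, and 0 of the 12 passed singly. Alox12 (-0.47, adjusted p = 0.146) and Mrvi1 (-0.34, adjusted p = 0.187) had the smallest p among them. The 13 erythroid genes were lower too (median -0.17, 12 below 0, camera adjusted p = 0.00694, adjusted p = 0.521 with an estimated correlation), so less blood of any kind in the mutant samples stays open beside it.

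Changed genes lay beside each other more often than chance. By the order of genes in GRCm38.p6, 21 pairs of neighbouring tested genes changed in the same direction, against a mean of 4.42 and a 95th percentile of 8 in 10000 random draws (permutation p = 0.0001, the smallest they can give). The pairs included Dlx3 with Dlx4 and Dlx4 with Dlx4os (higher), and Lhx8 with the unnamed transcript AI606473, Epha4 with Pax3, and Col6a2 with Col6a1 (lower). Genes of the macrophage and platelet shifts were among them too, such as C1qb with C1qc and C1qc with C1qa (higher) and Ppbp with Pf4 (lower). Shared regulation, duplicated genes of 1 family and a changed number of macrophages or platelets may each contribute to the 21 pairs. They were not separated here.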
